A study of Irpex lacteus with 9 samples.

How the data were processed

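RNA of *Irpex lacteus* grown on wheat straw was sequenced from 9 libraries, 3 each with distilled water, NH4Cl or NaNO3 added to the straw. Per the labels, polyadenylated RNA was purified with poly-T beads from 1 μg of total RNA for an Illumina library kit. The protocol text covers extraction from both plant and animal material without saying which route was used here. The labels do not say whether the replicates of a group were separate cultures, so p-values measure the spread between these samples only. The series title and the organism field name *Irpex lacteus*, while the design text names *Tricholoma album*, and the organism field was followed.

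The authors deposited 1 table of 19212 genes, 15316 named by locus tag and 3896 named as new genes. Per the submitters' processing notes HISAT2 and StringTie were used, with no versions given. The deposited counts are whole numbers per gene and library, read as raw counts. The deposited FPKM values, from the same table, were used for an alternative test and for choosing which genes to name. Per the file headers, further columns in other units hold the authors' DESeq2 log2 fold changes, adjusted p-values and calls at an FDR of 0.01 and a fold of 2. Their direction was checked against the counts, and the sign of the NH4Cl and NaNO3 pair was turned so that NH4Cl is compared with NaNO3. Annotation columns give product names, protein domains, KEGG pathways and GO terms. Of all genes, 6168 carry a named product, 3997 a KEGG pathway and 9980 a GO term.

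Depth was 17896230 to 23194078 counts per library. 2855 genes had no count in any library. 0 pairs of libraries were identical. Common biological variation between replicates was 0.317 (square root of the dispersion). A chi-square statistic per degree of freedom between replicate pairs ran from 45.2 to 478, against about 1 for counting noise, a value to which abundant genes add most.

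The choices of test, contrasts, gene lists and naming rule were fixed before the data were examined. The rule was to use counts if the table held them, and FPKM with limma otherwise. Counts were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest) in R 4.3.3, with all 9 libraries in 1 fit, no block, and 3 contrasts: NH4Cl with water, NaNO3 with water, and NH4Cl with NaNO3. 14808 genes passed the filter. A gene is called when its Benjamini-Hochberg (BH) adjusted p is under 0.05, and "rose", "fell", "higher" or "lower" without further words refers to called genes. Unless another tool is named, an adjusted p comes from edgeR. Levels are TMM-scaled CPM, given as mean ± SD with n = 3, and fold changes as log2 ± SE. The SE is the fitted log2 fold change before shrinkage divided by the square root of its F statistic. Levels come from scaled counts and fold changes from the fit, so the ratio of means can differ a little from the fold.

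There were 39 gene lists, built by matching fixed word patterns to 4 annotation columns. The lists of laccases and of wheat photosynthesis genes matched 0 genes, and nitric oxide detoxification matched 1, too few to test as a list. Each list with at least 5 tested genes was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. Beside it stand camera with an estimated correlation, and fry. Camera compares a list with all other genes, fry a list with no change. Counts of called members are given over all genes tested and adjusted over the list alone. Enrichment of KEGG pathways and GO terms used a one-sided Fisher exact test, over terms with 10 to 300 tested members, with the 3688 tested genes that have a KEGG pathway and the 8796 that have a GO term as backgrounds. Word patterns also picked up a few genes that do not belong to a list, and these are named where they are among the called members.

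Genes were named by a rule with 3 parts. The first part takes the 5 largest rises and the 5 largest falls per contrast among called genes whose groups do not overlap, with a mean FPKM of at least 10 in the higher group and a named product. The second takes the 2 called members of each list with the highest FPKM. The third takes the 6 members of the nitrate and ammonium lists with the highest FPKM, called or not. This gave 122 gene results, 88 of them called, of which the text prints a part, chosen in the order lignocellulose, nitrogen, growth. Members of enriched terms, the 4 genes shown library by library for lignocellulose, and the peroxidase and hydrolase called only with libraries left out, were chosen after their values were seen.

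The correlation of both contrasts with water was set against 100 simulated draws in which unchanged groups were compared with the same water libraries, since both contrasts share them. Unchanged groups give almost no calls, so the draws were not used to judge the number of shared calls. With only 3 water libraries, no disjoint sets of 2 could be given to the comparisons.

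The tests were also tested on simulated data, after the comparisons had first been run. In libraries with 200 genes changed, modelled on NH4Cl against water, edgeR ran 14808 genes and found 14% of the genes changed 2-fold and 78% of those changed 4-fold, with 2 false calls. DESeq2 ran 14789 genes and found 44% and 93% with 36 false calls, and limma ran 13503 and found 13% and 77% with 2. This was a single draw that took each gene independently, so it held no shifts shared by the genes of a library. Many changes of 2-fold were missed in it at this number of libraries.

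Alternatives were median-of-ratios scaling, no filter, a mean FPKM of at least 5, limma on log2(FPKM + 1) with a mean FPKM of at least 1 and with pseudocounts of 0.1 and 5, quantile normalization, no variance trend, only the 6 libraries of a contrast, a fold of at least 2, DESeq2 1.42.0, and each library left out in turn. For lists, they also include membership in at least 2 annotation columns. Leaving out NH4Cl replicate 3 and NaNO3 replicate 1 together, limma-voom with library weights, robust quasi-likelihood and, for KEGG enrichment, leaving out genes named as new were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No genome or transcript annotation was used, so no positions are given. Some genes of like name run parallel over the libraries, which copies that share counts and genes under common control would both give. A count of genes can therefore hold 1 gene more than once. Raw reads were not used here.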

Results

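*Irpex lacteus* is a white-rot fungus that breaks down the lignin, cellulose and hemicellulose of plant cell walls. Its transcripts were compared on wheat straw with water, with ammonium (NH4Cl) and with nitrate (NaNO3), at 3 libraries per group. Each pair of groups was compared, to ask which genes differ with the nitrogen source. In all 3 comparisons every called gene had groups that do not overlap, and such genes made up 28.0%, 33.0% and 25.2% of all tested genes in NH4Cl against water, NaNO3 against water and NH4Cl against NaNO3, where chance gives 10%.

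The question for the wood-decay enzymes is whether their transcripts follow the added nitrogen. Class II peroxidases, the enzymes that oxidise lignin, were among the most abundant transcripts. Their 15 genes took from 4.54% (95% CI 4.53 to 4.55) to 6.88% (6.87 to 6.90) of the counts in 7 libraries, 2.54% (2.53 to 2.55) in NH4Cl replicate 3 and 0.888% (0.884 to 0.893) in NaNO3 replicate 1. These intervals, and all others of shares of counts, cover counting error only and not the spread between replicates. The 23 genes of lytic polysaccharide monooxygenases and cellobiose dehydrogenase, which attack cellulose by oxidation, took 0.0652% (0.0641 to 0.0664) to 0.216% (0.214 to 0.218) in those 7 libraries, 0.793% (0.789 to 0.797) in NH4Cl replicate 3 and 0.381% (0.378 to 0.383) in NaNO3 replicate 1. For the 31 cellulases the shares were 0.0686% (0.0674 to 0.0698) to 0.147% (0.146 to 0.149), then 0.908% (0.904 to 0.912) and 0.234% (0.232 to 0.237). Versatile peroxidase VPS1 (NewGene_2774) stood at 18620 to 30330 CPM in 7 libraries, at 5958 in NH4Cl replicate 3 and at 397 in NaNO3 replicate 1, and VPL1 (BC629DRAFT_1589175) at 13090 to 20730, 4095 and 278 CPM. The 2 kept a ratio of 1.39 to 1.49 in all 9 libraries, so they are not sure to be separate results. Exoglucanase 1 (BC629DRAFT_1581701), a cellulase, stood at 2443 CPM in NH4Cl replicate 3 and at 11.4 to 74.2 CPM in the other 8 libraries. A further copy (BC629DRAFT_1582264) stood at 2361 CPM in NH4Cl replicate 3, 571 in NaNO3 replicate 1 and 18.1 to 431 in the others. By edgeR 0 members of these 3 lists were called in any comparison (1, 2 and 10 gene results at an unadjusted p under 0.05 for peroxidases, monooxygenases and cellulases; DESeq2: 0, 0 and 6; limma: 0; voom: 0, 0 and 2). Without NH4Cl replicate 3 and NaNO3 replicate 1, the libraries that stand apart in these shares, edgeR called 1 class II peroxidase and 1 cellulase, and 0 monooxygenases. A further VPS1 gene (BC629DRAFT_1589173) was then lower with NH4Cl than with water (log2 −2.23, adjusted p = 0.0278) and NaNO3 (−2.45, 0.0189), as was a family 9 glycoside hydrolase (BC629DRAFT_1291281; −0.82, 0.0221, and −0.82, 0.0192). These libraries were left out for their shares in these same lists, so the 2 calls are no independent support. In NaNO3 replicate 1 this VPS1 gene stood at 10.3 CPM, against 269 and 396 in NH4Cl replicates 1 and 2. In NH4Cl replicate 3 it stood at 42.5 CPM, below all water libraries (1296 to 1937), as did the other NH4Cl libraries. With all 9 libraries it was not called. The hydrolase stood at 53.0 CPM in NH4Cl replicate 3, above all water libraries (35.3 to 37.7).

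**Figure D1:**
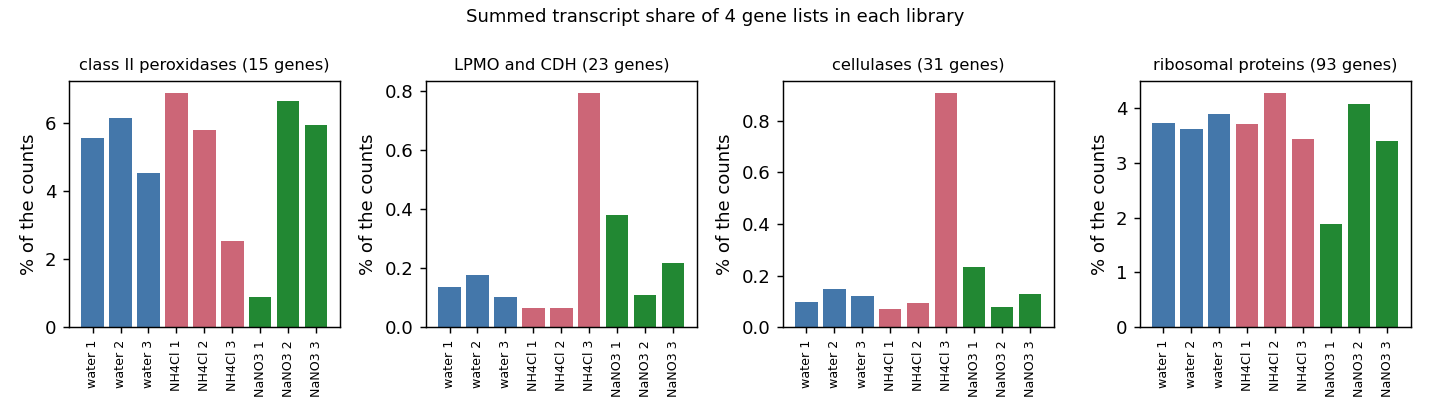
Share of each library's counts taken by 4 gene lists, 1 bar per library, coloured by group. NH4Cl replicate 3 and NaNO3 replicate 1 have low bars for class II peroxidases and high bars for monooxygenases and cellulases.

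**Figure D2:**
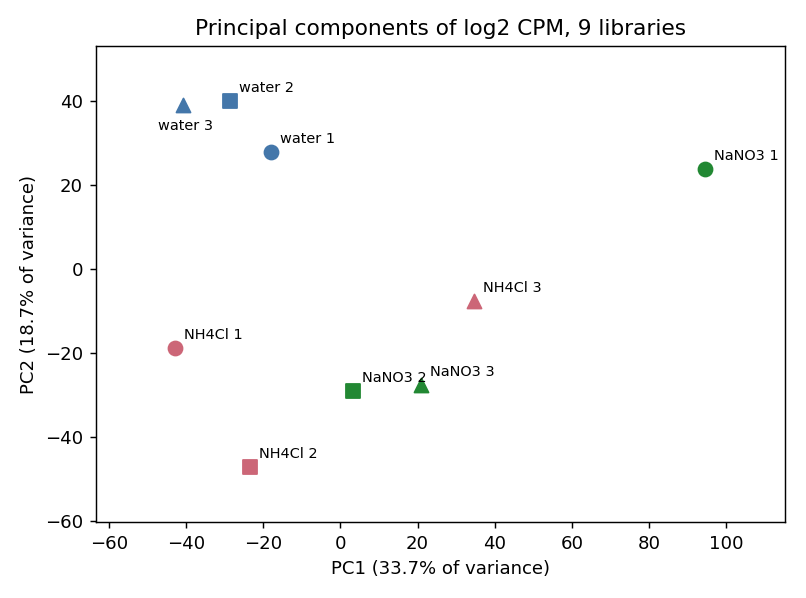
Principal components 1 and 2 of log2 CPM, 1 point per library, coloured by group with a symbol per replicate. NaNO3 replicate 1 lies apart from the other libraries along component 1. On these components NH4Cl replicate 3 lies away from the other NH4Cl libraries and near NaNO3 replicate 3. On component 3 (16.1% of variance, not drawn) it lies at −52.9, and NH4Cl replicates 1 and 2 at −24.9 and −20.5. NaNO3 replicates 1, 2 and 3 lie there at −1.77, 49.0 and 33.8.

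With ammonium, compared with water, the largest rise among the genes named was that of GLOX (BC629DRAFT_1598350), a copper radical oxidase that makes hydrogen peroxide for the peroxidases. It rose from 28.4 ± 15.8 to 454 ± 378 CPM (mean ± SD, n = 3), a log2 change of 4.0 ± 0.64 (SE), with NH4Cl libraries at 208, 265 and 890 CPM. Falls among the genes named include those of 3 fused cytochrome P450-reductases, enzymes that hydroxylate fatty acids and similar molecules: BC629DRAFT_1590402 fell from 39.0 ± 12.3 to 6.10 ± 3.2 CPM (log2 −2.68 ± 0.38), NewGene_3712 by a log2 change of −2.54 ± 0.41 and BC629DRAFT_1583529 by −2.30 ± 0.35. The 3,2-trans-enoyl-CoA isomerase (BC629DRAFT_1587930), needed for unsaturated fatty acids, fell from 709 ± 223 to 151 ± 54.0 CPM (log2 −2.23 ± 0.34), and mitochondrial fumarase (BC629DRAFT_1588922) from 584 ± 69.7 to 187 ± 53.7 CPM (log2 −1.65 ± 0.25). The secreted tripeptidyl-peptidase sed3 (BC629DRAFT_1579821) fell from 1824 ± 747 to 460.5 ± 35.5 CPM (log2 −1.99 ± 0.31). Smaller rises were those of the iron oxidase fer1 (NewGene_1730; 1.59 ± 0.274 to 6.44 ± 0.884 CPM, log2 2.01 ± 0.22) and the omega-3 desaturase (BC629DRAFT_163522; 20.6 ± 4.61 to 50.4 ± 13.4 CPM, log2 1.29 ± 0.22). Adjusted p for these genes lay between 0.0403 and 0.0452.

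In all, 41 genes were higher and 59 lower with NH4Cl than with water of 14808 tested by edgeR quasi-likelihood, and 2779 had an unadjusted p under 0.05. DESeq2 called 560 higher and 638 lower, and limma on FPKM 31 and 45. The count of calls changes with single libraries. NaNO3 libraries are among them, though they enter this comparison only through the filter, scaling and spread of the joint fit. By edgeR the count was 0 without water replicate 1 or 2, NH4Cl replicate 2, or NaNO3 replicate 2 or 3 (2388, 1874, 1916, 2677 and 2660 genes at an unadjusted p under 0.05). Without water replicate 3 it was 5 and without NH4Cl replicate 3 it was 30. Without NH4Cl replicate 1 or NaNO3 replicate 1 it was 290 and 365. With NH4Cl replicate 3 and NaNO3 replicate 1 both left out, 287 genes were higher and 478 lower, among them all 100 of the calls from the 9 libraries. In the authors' deposited DESeq2 columns 169 genes are higher and 266 lower at a fold of at least 2, of which 35 and 45 are shared with edgeR.

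By gene group, transporters that bring amino acids and peptides into the cell had the lowest p by camera with NH4Cl against water. Of 81 tested, 0 were called over all genes tested by edgeR, 1 was higher and 9 lower when adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher and 26 lower (DESeq2: 2 higher and 11 lower; limma: 0; voom with library weights: 2 and 19). Their median log2 change was −0.33 and camera placed them below other genes (adjusted p = 4.19e-05; adjusted p = 0.122 with an estimated correlation). By camera the adjusted p was at most 0.00172 without any 1 library. Fry, which asks whether a list changed at all and not whether it differs from other genes, gave 0.00483. The 20 genes of ammonium uptake and assimilation had a median of −0.35 and an adjusted p = 0.0123 by camera (adjusted p = 0.618 with an estimated correlation), which passed the threshold no longer without water replicate 1 (0.0635), NH4Cl replicate 1 (0.0546) or NH4Cl replicate 3 (0.0556). 0 of them were called over all genes tested, 5 were lower when adjusted over the list alone, and 1 was higher and 5 lower at an unadjusted p under 0.05 (DESeq2: 5 lower; limma: 0; voom: 5 lower). The ammonium transporter NewGene_3477 stood at 208 ± 160 CPM with water and 22.1 ± 2.23 with NH4Cl (log2 −3.24 ± 0.71, adjusted p = 0.0682), where water replicate 3 had 30.8 CPM against 253 and 341 in the other water libraries. Of the 8 nitrate assimilation genes 0 were called over all genes tested, and 1 was higher and 3 lower when adjusted over the list alone, as at an unadjusted p under 0.05 (DESeq2: 1 and 3; limma: 0; voom: 1 and 2). Of the 70 genes of other nitrogen source use 0 were called, over all genes tested or adjusted over the list alone, and camera gave an adjusted p = 0.259 with a median of −0.15. At an unadjusted p under 0.05, 3 were higher and 16 lower (DESeq2: 1 and 9; limma: 0; voom: 2 and 13).

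For the 71 genes of oxidative phosphorylation with NH4Cl against water the median was −0.21 and camera gave an adjusted p = 6.37e-05 (adjusted p = 0.816 with an estimated correlation), under the threshold without any 1 library. 1 of them was called over all genes tested and 9 were lower when adjusted over the list alone. The called gene is the external alternative NADH dehydrogenase (BC629DRAFT_1593480), which fell from 112 ± 12.8 to 59.9 ± 5.28 CPM (log2 −0.91 ± 0.14). Glycolysis genes (32) had a median of 0.35, above other genes by camera at an adjusted p = 0.000486 (adjusted p = 0.69 with an estimated correlation) and under the threshold without any 1 library. Of them 0 were called over all genes tested and 0 adjusted over the list alone by edgeR (5 higher at an unadjusted p under 0.05; DESeq2: 3 higher; limma: 0; voom: 4 higher). The 41 genes of fatty acid beta-oxidation had a median of −0.24 and an adjusted p = 0.00839 (adjusted p = 0.618 with an estimated correlation), at 0.0776 without NH4Cl replicate 3. 1 was called over all genes tested, the isomerase above, and 4 were lower when adjusted over the list alone.

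Ribosome biogenesis genes (193) had a median of −0.14 with NH4Cl against water and an adjusted p = 0.0196 by camera (adjusted p = 0.816 with an estimated correlation), at 0.0961 without water replicate 1, 0.0918 without water replicate 2, 0.0546 without NH4Cl replicate 1 and 0.0556 without NH4Cl replicate 3. Their 1 call over all genes tested (2 lower when adjusted over the list alone) is subunit 17 of Mediator (BC629DRAFT_1593736), a transcription protein caught by its annotation text. DNA replication and histone genes (43) had a median of 0.19 and an adjusted p = 0.00839 (adjusted p = 0.816 with an estimated correlation), at 0.169 without water replicate 3 and 0.0556 without NH4Cl replicate 3. 1 gene rose over all genes tested and 1 when adjusted over the list alone, DNA polymerase epsilon subunit B (BC629DRAFT_1583118; 4.84 ± 0.678 to 11.4 ± 2.22 CPM, log2 1.23 ± 0.21). Hemicellulases (47) had a median of 1.10 and an adjusted p = 0.0109 by camera (adjusted p = 0.816 with an estimated correlation), but 0.84 without NH4Cl replicate 3, 0.141 without water replicate 1 and 0.869 without both libraries that stand apart. The 5 dye-decolorizing peroxidases had a median of 1.12 and an adjusted p = 0.0345 (adjusted p = 0.618 with an estimated correlation), at 0.0918 without water replicate 2, 0.0518 without NH4Cl replicate 1, 0.0717 without NH4Cl replicate 2 and 0.0556 without NH4Cl replicate 3. 0 of either list were called over all genes tested by edgeR; adjusted over the list alone 0 hemicellulases and 3 dye-decolorizing peroxidases were higher, and 6 and 3 at an unadjusted p under 0.05 (DESeq2: 2 and 0; limma: 0; voom: 2 and 2).

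Among KEGG pathways, 7 of the 141 genes under tryptophan metabolism were lower with NH4Cl than with water (adjusted p = 0.000764) and 4 of the 65 under fatty acid degradation (adjusted p = 0.021). The first set is made up of the 3 fused P450-reductases, 3 genes named as itaconate transport proteins that carry a kynureninase annotation, and 1 gene with an indoleamine dioxygenase domain. The second is the 3 fused P450-reductases and the enoyl-CoA isomerase, so neither set is a run of steps in its pathway. NewGene_3712 and BC629DRAFT_1583529 carry the same name, and their log2 CPM correlate at 0.992 over the 9 libraries. The itaconate transport proteins NewGene_809 and BC629DRAFT_551280 correlate at 0.987. Whether either pair are copies that share counts, so that 1 gene is counted again, could not be checked without a genome. With all genes named as new left out, 4 of 108 and 3 of 50 genes were lower, and neither pathway passed (adjusted p = 0.116 for both). Of the itaconate transport proteins, BC629DRAFT_551280 fell from 55.2 ± 25.8 to 9.87 ± 3.11 CPM (log2 −2.48 ± 0.41). No pathway or term passed for genes higher with NH4Cl (lowest adjusted p = 0.981), and no GO term for genes lower (lowest 0.0502).

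With nitrate, compared with water, rises among the genes named include those of 3 glycolysis enzymes. Glyceraldehyde-3-phosphate dehydrogenase (NewGene_2934) rose from 143 ± 13.3 to 551 ± 212 CPM (n = 3), a log2 change of 1.95 ± 0.31, pyruvate kinase (BC629DRAFT_1588583) from 109 ± 26.8 to 400.2 ± 258 CPM (1.87 ± 0.42) and phosphoglycerate kinase (BC629DRAFT_1478689) from 107 ± 31.3 to 390 ± 201 CPM (1.86 ± 0.42). NaNO3 replicate 1 was the highest for each, at 791, 695 and 614 CPM. The other NaNO3 libraries stood at 388 to 475, 217.5 to 288 and 225 to 330 CPM. Falls among the genes named include those of abundant transcripts. Protein FDD123 (BC629DRAFT_1436974), an opsin-like membrane protein, fell from 2763 ± 653 to 99.9 ± 58.0 CPM (log2 −4.79 ± 0.78). The transcription factors SFP1 (BC629DRAFT_1437891) and RGT1 (BC629DRAFT_1515137), the second named for its control of glucose transport, fell from 1941 ± 287 to 91.4 ± 19.5 CPM (log2 −4.41 ± 0.72) and from 988 ± 227 to 59.5 ± 51.4 CPM (log2 −4.05 ± 0.80). A hexose transporter (BC629DRAFT_1596147) fell from 42.9 ± 16.6 to 9.18 ± 2.83 CPM (log2 −2.23 ± 0.35). Adjusted p for these genes lay between 0.0222 and 0.0445. FDD123, SFP1, RGT1 and the hexose transporter also stood lower in every NH4Cl library than in any water library, though none was called with NH4Cl against water. Their NH4Cl libraries ran from 226 to 1156, 97.7 to 634, 87.3 to 470 and 8.99 to 14.3 CPM.

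NaNO3 against water gave the most calls of the 3 comparisons: 174 genes were higher and 575 lower of 14808 tested by edgeR, and 3661 had an unadjusted p under 0.05. DESeq2 called 904 higher and 1034 lower, and limma on FPKM 48 and 334. Without water replicate 2 or 3 the edgeR count was 0 (2534 and 2604 genes at an unadjusted p under 0.05), and without NaNO3 replicate 2 or 3 it was 1 (3592 and 3272). Without water replicate 1 it was 386, without NH4Cl replicate 2 it was 432 and without NaNO3 replicate 1 it was 486, so each call ends when 1 of several libraries is left out. With NH4Cl replicate 3 and NaNO3 replicate 1 both left out, 394 genes were higher and 708 lower, 589 of them shared with the 749. The authors' deposited columns hold 143 higher and 516 lower, of which 70 and 401 are shared with edgeR.

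The proteasome, the complex that degrades proteins inside the cell, was the strongest group higher with NaNO3. 15 of the 52 genes of the KEGG pathway rose, where 1.0 would be expected by chance (adjusted p = 1.02e-12; 14 of 42 and 1.94e-12 with genes named as new left out), and 0 fell. The whole set had a median log2 change of 0.82, and 38 members were higher at an unadjusted p under 0.05 (DESeq2: 33 higher; limma: 5; voom: 31). Examples are subunit alpha 5 (BC629DRAFT_1284122; 51.4 ± 15.3 to 122 ± 31.1 CPM, log2 1.25) and beta 4 (BC629DRAFT_1586899; 39.6 ± 11.3 to 90 ± 17.0 CPM, log2 1.18). Called members numbered 0 without water replicate 2, water replicate 3, NaNO3 replicate 2 or NaNO3 replicate 3, 3 without NaNO3 replicate 1 or NH4Cl replicate 2, 23 without water replicate 1 and 9 without both libraries that stand apart. The median stayed between 0.65 and 0.98 without any 1 library.

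Glycolysis had 6 of 32 genes higher over all genes tested with NaNO3 against water and 13 when adjusted over the list alone (DESeq2: 13; limma: 2; voom: 10), with a median of 0.55. Camera gave an adjusted p = 3.32e-05 (adjusted p = 0.96 with an estimated correlation), under the threshold without any 1 library, and 7 of the 64 genes of the wider KEGG pathway rose and 2 fell (adjusted p for the rises = 0.00942; 5 of 54 and 0.154 with genes named as new left out; 0.272 with the calls of limma). At an unadjusted p under 0.05, 18 of the 64 were higher and 10 lower (DESeq2: 17 and 2; limma: 3 and 0; voom: 13 and 9). DNA replication and histone genes had a median of 0.52 and an adjusted p = 2.23e-08 (adjusted p = 0.96 with an estimated correlation), also under the threshold without any 1 library. 3 of 43 were higher and 1 lower over all genes tested, 6 and 1 when adjusted over the list alone. Histone H2A (BC629DRAFT_1294244) rose from 114 ± 31.8 to 262 ± 60.8 CPM (log2 1.20 ± 0.26). Cytosolic ribosomal proteins (93) had a median of −0.27 and an adjusted p = 0.00634 by camera (adjusted p = 0.96 with an estimated correlation), but the direction turned without NaNO3 replicate 1 (0.291), which had 1.89% (95% CI from counting error only, 1.89 to 1.90) of its counts in these genes against 3.41% (3.40 to 3.42) to 4.29% (4.28 to 4.30) elsewhere. 0 of them were called by edgeR, limma, DESeq2 or voom, and 0 at an unadjusted p under 0.05 or when adjusted over the list alone.

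Peroxisomes are where long-chain fatty acids are broken down. With NaNO3 against water 17 of the 87 genes of their KEGG pathway fell (adjusted p = 9.25e-08; 13 of 75 and 1.87e-05 with genes named as new left out) and 0 rose. At an unadjusted p under 0.05, 7 were higher and 23 lower (DESeq2: 5 and 19; limma: 0 and 9; voom: 4 and 20). Without both libraries that stand apart 3 were called higher and 12 lower. Called lower were 8 without water replicate 1 or NaNO3 replicate 1, and 0 without water replicate 2 or 3 or NaNO3 replicate 2 or 3. A peroxisomal targeting signal receptor (BC629DRAFT_1473385) fell from 89.6 ± 8.50 to 32.1 ± 4.05 CPM (log2 −1.48). With NH4Cl against water 2 of the 87 genes were called lower by edgeR. At an unadjusted p under 0.05, 4 were higher and 21 lower there (DESeq2: 1 and 12). In fatty acid degradation 13 of 65 genes fell with NaNO3 against water (adjusted p = 3.83e-06; 8 of 50 and 0.0046 with genes named as new left out). Among the 13 were the fused P450-reductases and the enoyl-CoA isomerase, the genes called there with NH4Cl. At an unadjusted p under 0.05, 1 was higher and 24 lower, and 2 and 22 with NH4Cl against water (DESeq2: 1 and 16, and 0 and 17). The 6 of 28 under fatty acid biosynthesis with NaNO3 (adjusted p = 0.00666) are all long-chain acyl-CoA synthetases, and with genes named as new left out 2 of 22 fell (adjusted p = 1.0). That pathway also did not pass with median-of-ratios scaling (3 fell, adjusted p = 0.558) or with the calls of limma (2 fell, adjusted p = 1.0). In the fixed list of beta-oxidation, 2 of 41 genes were lower over all genes tested and 2 when adjusted over the list alone: the enoyl-CoA isomerase (log2 −2.67 ± 0.35) and peroxisomal thiolase (BC629DRAFT_1276227; 312 ± 22.4 to 158 ± 17.6 CPM, log2 −0.98 ± 0.18). Among GO terms, 16 of 104 transcription factors specific to RNA polymerase II were lower (adjusted p = 0.000179), a term that also holds a septin and an RCC1 protein, as were 18 of 133 genes under host cell nucleus (0.000179) and 5 of 14 under mitochondrial intermembrane space (0.0225). 8 of 17 threonine-type endopeptidases, which are proteasome subunits, were higher (4.08e-08). Of the 104 transcription factors, 2 were higher and 32 lower with NaNO3 against water at an unadjusted p under 0.05 (DESeq2: 1 and 22). With NH4Cl against water 2 were called lower by edgeR, and at that bound 3 were higher and 28 lower (DESeq2: 1 and 20). Between NH4Cl and NaNO3 0 of them were called by edgeR.

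Few nitrogen genes were called between NaNO3 and water. Of the ammonium genes, 1 of 20 was higher over all genes tested and 2 when adjusted over the list alone; the called gene carries a glutamine synthetase and guanido kinase domain (BC629DRAFT_1596891; 5.58 ± 1.69 to 17.3 ± 5.62 CPM, log2 1.63 ± 0.34). Of the 8 nitrate assimilation genes 0 were called by edgeR, over all genes tested or adjusted over the list alone (3 higher at an unadjusted p under 0.05; DESeq2 and limma: 0; voom: 2). The nitrate reductase BC629DRAFT_1283050 stood at 34 ± 4.49 CPM with water and 60.3 ± 11.4 with NaNO3 (log2 0.83 ± 0.35, adjusted p = 0.186) and the nitrite reductase BC629DRAFT_1591045 at 47.5 ± 0.848 and 39.3 ± 6.85 (log2 −0.27 ± 0.16, adjusted p = 0.309). A urea transporter (BC629DRAFT_1277323) rose from 25.3 ± 3.89 to 62.1 ± 19.9 CPM (log2 1.30 ± 0.25). D-amino-acid oxidase (BC629DRAFT_1499854) fell from 63.9 ± 10.6 to 11.3 ± 2.49 CPM (log2 −2.49 ± 0.49) and a lysine permease (BC629DRAFT_238992) from 502 ± 47.2 to 161 ± 45.3 CPM (log2 −1.64 ± 0.26). In the lists these genes come from, 1 of 70 genes of other nitrogen source use was higher and 2 lower, over all genes tested and when adjusted over the list alone. Of 81 amino acid and peptide transporters, 3 were lower by either adjustment.

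**Figure D3:**
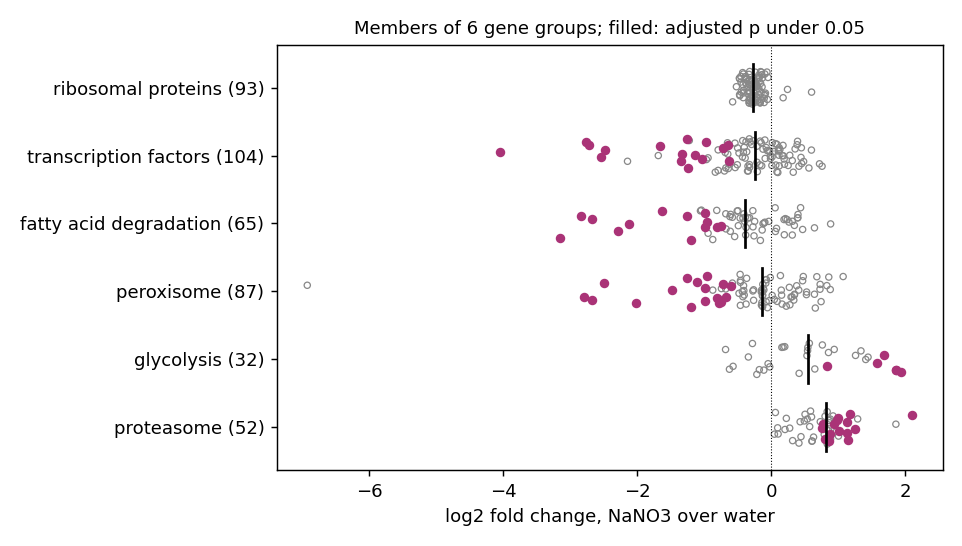
Log2 fold change of NaNO3 over water for each member of 6 gene groups, 1 point per gene, with the median as a bar. Filled points are called genes, which lie to the right for the proteasome and glycolysis and to the left for peroxisome genes and transcription factors.

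Between ammonium and nitrate, genes that take up and release nitrogen were among those called. The ammonium transporters NewGene_3477 and BC629DRAFT_1596464 stood at 22.1 ± 2.23 and 3.39 ± 0.533 CPM (n = 3) with NH4Cl and at 436 ± 72.1 and 78.9 ± 34.7 with NaNO3, log2 changes of −4.30 ± 0.74 and −4.54 ± 0.81. A nitrate transporter (BC629DRAFT_1580917) fell from 6.07 ± 1.95 CPM with NaNO3 to 0.407 ± 0.158 with NH4Cl (log2 −3.89 ± 0.54) and the nitrate reductase BC629DRAFT_1283050 from 60.3 ± 11.4 to 15.2 ± 7.13 (log2 −1.99 ± 0.36). Agmatinase (BC629DRAFT_1281437), the urease accessory protein UreG (BC629DRAFT_1714520) and the peptide transporter ptr2 (BC629DRAFT_1288078) were lower with NH4Cl, with log2 changes of −2.56 ± 0.38, −3.21 ± 0.49 and −1.98 ± 0.37. For ptr2, NaNO3 replicate 1 stood at 556 CPM and the other NaNO3 libraries at 187 and 241, against 82.3 to 84.9 with NH4Cl. Higher with NH4Cl were a chitin deacetylase (BC629DRAFT_1716602; 21.9 ± 3.53 with NaNO3 and 567 ± 478 CPM with NH4Cl, log2 4.69 ± 0.80, NH4Cl libraries at 292, 291 and 1119) and GLOX (32.4 ± 3.53 and 454 ± 378 CPM, log2 3.81 ± 0.63).

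**Figure D4:**
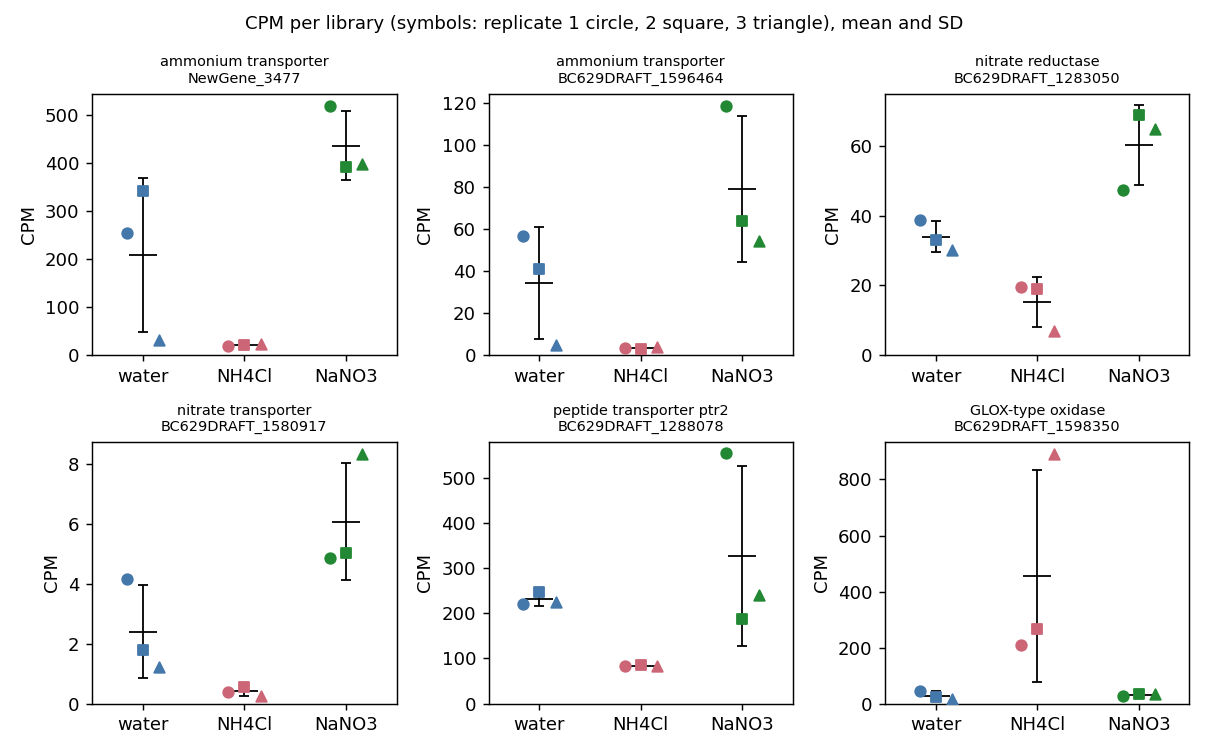
CPM of 6 genes in each of the 9 libraries, by group, with mean and SD. Both ammonium transporters, the nitrate reductase, the nitrate transporter and the peptide transporter are lowest with NH4Cl, GLOX is highest there, and water replicate 3 lies low for the ammonium transporters.

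In all, 88 genes were higher and 74 lower with NH4Cl than with NaNO3 by edgeR, and 3125 of 14808 had an unadjusted p under 0.05. DESeq2 called 703 higher and 715 lower, and limma on FPKM 69 and 46. Without NH4Cl replicate 2 the edgeR count was 0 (2332 genes at an unadjusted p under 0.05). Without water replicates 1, 2 and 3 in turn it was 44, 16 and 85, and without NaNO3 replicates 1, 2 and 3 in turn 92, 20 and 13. It was 30 without NH4Cl replicate 1 and 535 without NH4Cl replicate 3. With NH4Cl replicate 3 and NaNO3 replicate 1 both left out, 285 genes were higher and 525 lower, 140 of them shared with the 162. The authors' deposited columns hold 172 higher and 122 lower, of which 73 and 61 are shared with edgeR.

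Of the 20 ammonium genes, 2 were lower with NH4Cl than with NaNO3 over all genes tested and 6 when adjusted over the list alone. The 2 are the ammonium transporters above, whose log2 CPM correlate at 0.99 (ratio of CPM 4.38 to 8.31), and whether they share counts could not be checked. The list had a median of −0.46 and an adjusted p = 5.73e-05 by camera (adjusted p = 0.11 with an estimated correlation; 0.00857 by fry), under the threshold without any 1 library and at 0.00125 without both libraries that stand apart. Amino acid and peptide transporters had 2 of 81 lower by either adjustment, a median of −0.21 and an adjusted p = 0.000198 (adjusted p = 0.11 with an estimated correlation; 0.0157 by fry), again under the threshold without any 1 library. In other nitrogen source use, 1 of 70 was higher and 4 lower over all genes tested, 3 and 8 when adjusted over the list alone, with a median of −0.34 and an adjusted p = 0.00273 (adjusted p = 0.831 with an estimated correlation), at 0.0595 without NH4Cl replicate 3. Nitrate assimilation had 2 of 8 lower over all genes tested, and 1 higher and 2 lower when adjusted over the list alone. The glutamine synthetases NewGene_1883 and BC629DRAFT_780516 stood at 268 ± 26.3 and 323 ± 38.9 CPM with NH4Cl and 534 ± 42.6 and 592 ± 47.0 with NaNO3 (log2 −1.0 ± 0.23 and −0.87 ± 0.23, adjusted p = 0.0727 and 0.0883). Their CPM kept a ratio of 0.81 to 0.91 in all 9 libraries (correlation of log2 CPM 0.997), so these are not sure to be separate results: whether they are copies that share counts could not be checked. Glutamate synthase (BC629DRAFT_1587885) stood at 301 ± 27.4 and 296 ± 42.5 (log2 0.02 ± 0.23, adjusted p = 0.967).

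In growth-related lists few genes were called between NH4Cl and NaNO3. Ribosomal protein genes had a median of 0.23 and an adjusted p = 0.0021 by camera (adjusted p = 0.831 with an estimated correlation), at 0.0579 without NH4Cl replicate 2 and turned in direction without NaNO3 replicate 1 (0.0795). 0 of 93 were called by edgeR over all genes tested or adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by limma, DESeq2 and voom. DNA replication and histone genes had a median of −0.33 and an adjusted p = 0.000803 (adjusted p = 0.831 with an estimated correlation), under the threshold without any 1 library. Of them 0 were called over all genes tested and 1 was higher when adjusted over the list alone (1 higher and 8 lower at an unadjusted p under 0.05; DESeq2: 1 and 3; limma: 0; voom: 1 higher). Oxidative phosphorylation had 1 of 71 lower by either adjustment, the alternative NADH dehydrogenase again (log2 −0.84 ± 0.14). The list had a median of −0.11 and an adjusted p = 0.00812 (adjusted p = 0.831 with an estimated correlation), at 0.141 without NH4Cl replicate 3. Glutathione S-transferases had 1 of 48 lower over all genes tested and 3 when adjusted over the list alone. Their median was −0.40, with an adjusted p = 0.0103 (adjusted p = 0.831 with an estimated correlation), at 0.123 without NH4Cl replicate 3, 0.221 without NaNO3 replicate 2 and 0.0857 without NaNO3 replicate 3. Mitochondrial manganese superoxide dismutase (BC629DRAFT_1599606) was at 68.4 ± 22.2 CPM with NH4Cl and 198 ± 25.7 with NaNO3 (log2 −1.53 ± 0.24). The 1 GO term that passed, 4 of 22 hydrolases of carbon-nitrogen bonds other than peptide bonds (adjusted p = 0.0107), holds 3 chitin deacetylases, NewGene_2243 (log2 −1.49), NewGene_2244 (log2 −1.25) and BC629DRAFT_1442315 (log2 −1.34), and a guanine deaminase. These deacetylases fell while BC629DRAFT_1716602 rose. No KEGG pathway passed (lowest adjusted p = 0.71). Of the 52 proteasome genes 0 were called by edgeR, but their median was −0.627, and 0 were higher and 37 lower at an unadjusted p under 0.05 (DESeq2: 20 lower; limma: 0; voom: 5 lower; edgeR without both libraries that stand apart: 1 lower).

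For the lists that act on lignocellulose, results over the 3 comparisons together are counts of gene results by edgeR over all genes tested, adjusted over the list alone, at an unadjusted p under 0.05, by DESeq2, by limma and by voom, in this order. They were 0, 0, 1, 0, 0 and 0 for class II peroxidases, 0, 5, 5, 2, 0 and 3 for dye-decolorizing peroxidases, and 0, 0, 2, 0, 0 and 0 for monooxygenases and cellobiose dehydrogenase. Cellulases had 0, 0, 10, 6, 0 and 2, beta-glucosidases (23 genes) 0, 3, 14, 3, 0 and 6, hemicellulases 0, 0, 16, 6, 0 and 3, pectinases (20) 0, 3, 11, 9, 0 and 8, and starch, glycogen and trehalose breakdown (14) 0, 0, 4, 1, 0 and 0. Oxalate and formate metabolism (10) had 0, 7, 10, 4, 0 and 7, and sugar transporters (49) 2, 4, 35, 11, 1 and 12, the 2 being the hexose transporter with NaNO3 and a siderophore transporter (BC629DRAFT_498890) caught by its annotation text. The 44 oxidases that produce hydrogen peroxide had 4, 8, 37, 22, 4 and 16: GLOX in both comparisons with NH4Cl, and 2 galactose oxidase domain genes that fell with NaNO3 against water, NewGene_2209 (382 ± 54.0 to 175 ± 28.3 CPM, log2 −1.13 ± 0.20) and BC629DRAFT_1529016 (log2 −1.04 ± 0.18). The 2 kept a ratio of 1.04 to 1.21 in all 9 libraries, so they are not sure to be separate results. Aromatic compound catabolism (84) had 5, 13, 54, 27, 5 and 29, among them the dehydrogenase orsE (BC629DRAFT_1517966), higher with NH4Cl than with NaNO3 (62.7 ± 7.42 and 17.4 ± 3.72 CPM, log2 1.85 ± 0.22). Cytochromes P450 (152) had 13, 17, 78, 39, 9 and 44, with himC (BC629DRAFT_567127) falling from 323 ± 108 with water to 61.4 ± 25.3 CPM with NH4Cl (log2 −2.39 ± 0.42) and P450 61 (BC629DRAFT_1580530) from 479 ± 156 to 152 ± 46.0 CPM with NaNO3 (log2 −1.66 ± 0.34). Glutathione S-transferases had 4, 6, 28, 12, 1 and 17, antioxidant enzymes (42) 5, 14, 32, 25, 5 and 22, and chitin and glucan enzymes of the cell wall (59) 7, 17, 49, 31, 5 and 27, of which a phenol hydroxylase (NewGene_1414) does not belong to the list.

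The medians of the cellulose-degrading lists depend on the same libraries that stand apart, and on the model. For monooxygenases and cellobiose dehydrogenase with NH4Cl against water the median was 1.63 and, without both libraries, −1.45, for cellulases 1.58 and −0.52, and for hemicellulases 1.10 and −0.20. With NH4Cl against NaNO3 the monooxygenase list had a median of 0.34 and, without both libraries, −1.93, and cellulases 0.755 and −0.424. The mean of the monooxygenase list was 0.34, while camera gave a downward direction (adjusted p = 0.516). With NaNO3 against water its median was 1.40 and, without both libraries, 0.40. With a replicate block the medians of the monooxygenase list were 0.078 with NH4Cl against water, 0.287 with NaNO3 against water and −0.315 with NH4Cl against NaNO3. Those of cellulases were 0.475, 0.277 and 0.246.

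In the same order, the remaining nitrogen and growth lists had the following counts. Molybdenum cofactor synthesis (6) had 0, 1, 4, 2, 0 and 3, nitric oxide detoxification (1) 0 throughout, nitrogen regulators (9) 0, 2, 6, 2, 0 and 6, secreted peptidases (146) 3, 14, 100, 42, 1 and 50, and amino acid biosynthesis (112) 7, 19, 76, 45, 3 and 52. The last includes argininosuccinate lyase (BC629DRAFT_1015859), which rose with NaNO3 (63.6 ± 10.3 to 103 ± 10 CPM, log2 0.70 ± 0.16), and isocitrate dehydrogenase subunit 1 (BC629DRAFT_1638504), a citrate cycle enzyme that fell with NH4Cl (log2 −1.10 ± 0.17). Aminoacyl-tRNA synthetases (65) had 3, 6, 35, 15, 3 and 14, the called ones being 2 FDD123 genes and a gene with a domain of unknown function, all 3 caught by annotation text and not synthetases. Ribosome biogenesis had 9, 7, 113, 44, 3 and 62, and citrate and glyoxylate cycles (50) 5, 29, 51, 35, 2 and 38. Oxidative phosphorylation had 4, 10, 40, 26, 0 and 28 and ergosterol synthesis (35) 1, 0, 21, 10, 0 and 9. The 1 gene called in the ergosterol list is named as the P450 FUM15 (BC629DRAFT_372385) and was matched by annotation text. Its name is not that of an ergosterol enzyme. The word pattern of that list did not catch BC629DRAFT_1646314 and NewGene_3410, both named as sterol desaturases, which fell with both salts against water. Their log2 changes were −1.71 and −1.65 with NH4Cl and −1.36 and −1.31 with NaNO3. Heat shock proteins and chaperones (128) had 9, 17, 88, 43, 6 and 49, with mitochondrial HSP60 (BC629DRAFT_1442395) falling from 154 ± 11.2 to 66.5 ± 8.58 CPM with NaNO3 (log2 −1.21 ± 0.21). Hydrophobins (13) had 0, 0, 5, 2, 0 and 2, and pheromone and mating genes (11) 0, 1, 4, 1, 0 and 2.

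Medians, means and camera directions did not share a sign in some lists, none of which passed. In NH4Cl against water these were hydrogen peroxide producing oxidases, cell wall enzymes, cytochromes P450, nitrogen regulators, aminoacyl-tRNA synthetases, ribosomal proteins and heat shock proteins. In NaNO3 against water they were hydrogen peroxide producing oxidases, pectinases, cell wall enzymes, aromatic compound catabolism, oxalate and formate metabolism, nitrate assimilation, aminoacyl-tRNA synthetases, citrate and glyoxylate cycles and pheromone genes. In NH4Cl against NaNO3 they were hydrogen peroxide producing oxidases, monooxygenases, cell wall enzymes, oxalate and formate metabolism, cytochromes P450, secreted peptidases and aminoacyl-tRNA synthetases. With median-of-ratios scaling the sign of a median turned for ribosomal proteins in NH4Cl against water and for cell wall enzymes, cytochromes P450, amino acid and peptide transporters, pheromone genes and KEGG tryptophan metabolism in NaNO3 against water, all of them medians near 0.

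Among the genes that fell with both salts against water were the fused P450-reductases, the enoyl-CoA isomerase and fumarase. BC629DRAFT_1590402, BC629DRAFT_1587930 and BC629DRAFT_1588922 stood at 5.47 ± 1.05, 112 ± 28.2 and 234 ± 43.2 CPM with NaNO3. Others were the P450 himC (BC629DRAFT_567127; log2 −2.39 with NH4Cl and −2.09 with NaNO3) and the itaconate transport protein BC629DRAFT_551280 (−2.48 and −1.96). To ask whether both nitrogen sources act on the same genes, calls were counted by direction: 6 genes were higher in both comparisons, 43 lower in both and 0 opposite. Lists drawn independently would share 0.482 and 2.29 genes, but both comparisons use the same water libraries, so this does not show that both sources act on the same genes. Across genes the correlation of log2 changes was 0.519, against 0.499 on average and 0.562 at most in unchanged groups simulated against the same water libraries, so the correlation itself lies within what the shared water libraries give. The covariance was 0.272, above the draws (0.115 on average and 0.137 at most). The draws took each gene independently. In the data, deviations of NH4Cl replicate 3 and NaNO3 replicate 1 from their group means correlated at 0.46, so no cause is read from the covariance. The 49 shared genes numbered 0 without any 1 of the 3 water libraries, NH4Cl replicate 2, NaNO3 replicate 2 or NaNO3 replicate 3. They numbered 5 without NH4Cl replicate 3, 101 without NaNO3 replicate 1 and 181 without NH4Cl replicate 1. A total of 180 genes were shared with both libraries that stand apart left out, 40 others then being opposite.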

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

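Leaving out NH4Cl replicate 3 and NaNO3 replicate 1 together, limma-voom with library weights, robust quasi-likelihood, leaving genes named as new out of the enrichment, and carrying all settings over to the overlap and the enrichment were chosen after seeing the data. For the counts below, the cause was not tested unless fewer libraries or another tool's power is the difference itself. The self-test gives a measure of that power only for a single draw of independent genes, without libraries that stand apart. In it DESeq2 found 44% of 2-fold changes with 36 false calls where edgeR found 14% with 2.

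Named genes mostly kept their direction. Over the alternatives other than leaving out a library, 1032 gene results kept direction and side of the threshold, 416 kept direction without a call, 7 gained a call and 0 reversed. With 1 library left out the numbers were 534, 552, 3 and 9 reversed, and under the added alternatives 341, 9, 13 and 3 reversed. All reversals are genes that were not called. With both libraries that stand apart left out, the nitrate reductase BC629DRAFT_53870 went from 0.185 to −0.173 with NH4Cl against water (−0.015 with limma-voom and library weights), and glutamate synthase BC629DRAFT_1587885 from 0.021 to −0.068 with NH4Cl against NaNO3. With 1 library left out, glutamate synthase ran from −0.05 to 0.131 in NH4Cl against NaNO3, from −0.262 to 0.13 in NH4Cl against water and from −0.283 to 0.109 in NaNO3 against water. The nitrate reductase BC629DRAFT_53870 ran from −0.142 to 0.411 in NH4Cl against water, BC629DRAFT_1591999 from −0.639 to 0.178 in NH4Cl against NaNO3, and NewGene_1332 from −0.397 to 0.05 in NaNO3 against water. The cause was not tested.

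Counts of called genes moved with the tool. By DESeq2, 560 genes were higher and 638 lower with NH4Cl than water, 904 and 1034 with NaNO3 than water, and 703 and 715 with NH4Cl than NaNO3. Limma-voom with library weights called 716 and 1208, 763 and 1521, and 479 and 585. With both libraries that stand apart left out, edgeR called 287 and 478 with NH4Cl against water, 394 higher with NaNO3 than water, and 285 and 525 with NH4Cl against NaNO3. Limma on log2(FPKM + 1) called 48 higher and 334 lower with NaNO3 than water, and 46 lower with NH4Cl than NaNO3.

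Other limma settings moved the counts as follows. A pseudocount of 0.1 gave 8 higher and 8 lower with NH4Cl than water, 46 and 316 with NaNO3 than water, and 42 lower with NH4Cl than NaNO3. A pseudocount of 5 gave 42 and 339 with NaNO3 than water and 43 lower with NH4Cl than NaNO3. Quantile normalization gave 67 higher with NH4Cl than water. Without the variance trend, 39 were lower with NH4Cl than water, 44 and 328 higher and lower with NaNO3 than water, and 40 lower with NH4Cl than NaNO3. Without a filter limma called 5 and 4, 24 and 296, and 39 lower with NH4Cl than NaNO3.

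In edgeR, no filter gave 18 genes lower with NH4Cl than water. A mean FPKM of at least 5 gave 36 lower with NH4Cl than water and 362 lower with NaNO3 than water. With only the 2 groups compared, so that 6 libraries give the spread, 6 were higher and 4 lower with NH4Cl than water, 82 higher with NaNO3 than water, and 4 higher and 8 lower with NH4Cl than NaNO3. A fold of at least 2 left 68 genes higher with NaNO3 than water. Median-of-ratios scaling and robust quasi-likelihood kept each count of calls within 1.5 times, and no setting shifted the median of all genes by 0.1 or more (at most 0.0738 in size).

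The replicate numbers of the titles showed no clear pairing of the libraries across groups. With 3 libraries per group a weak pairing could not be excluded. After each group's mean was taken out, correlations between libraries of the same number ran from −0.28 to 0.286, with 1 of 9 over 0.1, and 3 of 9 libraries correlated best with one of their own number. With a replicate block, edgeR called 0 and 0 genes with NH4Cl against water (2444 at an unadjusted p under 0.05), 0 and 0 with NaNO3 against water (3205), and 3 higher and 0 lower with NH4Cl than NaNO3 (2643), 0 genes in the overlap, and 0 KEGG terms passed. The block takes degrees of freedom from the spread, and it also moved the medians of the cellulose-degrading lists. The self-test found 3% of 2-fold and 64% of 4-fold changes with it.

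With 1 library left out, which assumes that the remaining pair varies like the other groups, calls ran from 0 to 163 higher and 0 to 202 lower with NH4Cl than water, from 0 to 208 and 0 to 509 with NaNO3 than water, and from 0 to 236 and 0 to 299 with NH4Cl than NaNO3. Genes called in both comparisons with water ran from 0 to 181, and KEGG terms passing from 0 to 10. Fewer libraries explain part of a loss, but the counts also rose without NH4Cl replicate 3 (535 between NH4Cl and NaNO3) or without NaNO3 replicate 1 (365 with NH4Cl against water).

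The overlap of 49 genes became 6 with a pseudocount of 0.1, 29 without the variance trend, 2 with limma and no filter, 15 with edgeR and no filter, 31 with a mean FPKM of at least 5, 32 with median-of-ratios scaling, 2 with only the groups compared, 480 by DESeq2, 180 with both libraries that stand apart left out and 806 by limma-voom with library weights. The 7 KEGG terms that passed became 3 with a pseudocount of 0.1, 4 with a pseudocount of 5, 3 with limma and no filter, 3 with edgeR and no filter, 23 by DESeq2, 22 with both libraries left out, 18 by limma-voom, 6 with median-of-ratios scaling, where fatty acid biosynthesis was lost, and 3 with genes named as new left out, which also takes out genes that are no copies. The cause was not tested.

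For gene lists the estimated correlation made the largest difference. By camera with the preset correlation 9 lists passed with NH4Cl against water, 3 with NaNO3 against water and 7 with NH4Cl against NaNO3, while with an estimated correlation 0, 0 and 0 did (lowest adjusted p = 0.122, 0.96 and 0.11) and by fry 1, 0 and 2. Leaving out 1 library gave 3 to 10, 3 to 5 and 5 to 11 lists, and leaving out both that stand apart gave 5 with NaNO3 against water. List results kept direction and side in 56 cases and lost the call in 38 under the alternatives fixed earlier, and in 147 and 22 with 1 library left out, where 2 reversed. The reversals are ribosomal proteins without NaNO3 replicate 1. Their adjusted p ran from 1.62e-10 to 0.291 with NaNO3 against water (0.256 and reversed with both libraries left out) and from 8.06e-12 to 0.0795 with NH4Cl against NaNO3. NaNO3 replicate 1, with the lowest share of counts in these genes, carries that direction.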

Other observations

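Tests of explanations reported here, other splits of the samples included, were chosen after the results were seen. Fatty acid desaturases and a gene of polyketide synthesis were among those called. The delta-12 desaturase (BC629DRAFT_1275853), which makes linoleic acid, stood at 20.8 ± 5.02 CPM with water, 56.7 ± 18.4 with NH4Cl and 10.4 ± 2.93 with NaNO3, and was higher with NH4Cl than with NaNO3 (log2 2.44 ± 0.33, adjusted p = 0.0225). The omega-3 desaturase (BC629DRAFT_163522) rose with both salts against water, to 43.5 ± 1.70 CPM with NaNO3 (log2 1.08 ± 0.22, adjusted p = 0.0351). Diels-Alderase ucsH (BC629DRAFT_676559), named after an enzyme of polyketide synthesis, stood at 9.37 ± 3.48, 29.1 ± 1.22 and 6.50 ± 1.69 CPM with water, NH4Cl and NaNO3, and was called in both comparisons with NH4Cl (log2 1.63 ± 0.27 and 2.16 ± 0.28).

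Among the genes called lower with NH4Cl than with NaNO3 were a secreted peptidase, agmatinase and a urease accessory protein, which were not tested as a group. The secreted peptidyl-Lys metalloendopeptidase (BC629DRAFT_1543585) stood at 1.65 ± 0.246 CPM with NH4Cl and 44.6 ± 35.8 with NaNO3 (log2 −4.75 ± 0.84, adjusted p = 0.0448). Its NaNO3 replicate 1 stood at 86.0 CPM and the other NaNO3 libraries at 24.6 and 23.3. Agmatinase (BC629DRAFT_1281437) stood at 64.0 ± 32.2, 18.1 ± 1.48 and 107 ± 2.79 CPM with water, NH4Cl and NaNO3, and the urease accessory protein UreG (BC629DRAFT_1714520) at 5.64 ± 3.49, 1.96 ± 0.498 and 18.1 ± 2.39. Water replicate 3 lay within the range of the NH4Cl libraries for UreG (1.844 against 1.534 to 2.506 CPM) and for the metalloendopeptidase (1.565 against 1.478 to 1.931 CPM). Secreted peptidases as a list did not go with these genes: the median against NaNO3 was 0.081, and at an unadjusted p under 0.05, 26 were higher and 13 lower (DESeq2: 9 and 5). Without NH4Cl replicate 2 no gene was called between NH4Cl and NaNO3 by edgeR, these included (2332 genes at an unadjusted p under 0.05).

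NH4Cl replicate 3 and NaNO3 replicate 1 had high transcripts of cellulose-degrading genes and low class II peroxidases beside the others of their groups. A swap of both labels may be set aside: of 808 genes that separate NH4Cl from NaNO3 without these libraries, 48.6% lay closer to the other group in NH4Cl replicate 3 but 19.43% in NaNO3 replicate 1, and a swap needs both out of place. The first form of this test asked for under 25% in each library and decided nothing, and was changed after its values were seen. A single wrong label of NH4Cl replicate 3 stays open from that share, although its ammonium transporters (24.2 and 3.91 CPM), nitrate reductase (6.96 CPM) and nitrate transporter (0.254 CPM) lie with NH4Cl. For library size or a few genes taking most counts, the monooxygenase list was followed through TMM scaling. Its median stayed 5.14 (NH4Cl replicate 3) and 2.087 (NaNO3 replicate 1) log2 units above the others of the group (5.30 and 2.42 before). The TMM factors were 1.08 and 1.19, so scaling could hardly have removed such differences. These libraries were also picked out by this list among others. The test could therefore not decide, and shows only that differences in scale were small beside the shift of the list. This test replaced a first one on the median of all genes (0.172 and 0.345, bound 0.3) that had decided nothing. Growth stage or sampling of the straw was not tested, since the design gives no such group.

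Of 52 proteasome genes 15 were higher with NaNO3 than with water. Scaling is unlikely to be the whole cause, as their median log2 change was at least 0.791 with median-of-ratios scaling and quantile normalization. NaNO3 replicate 1 alone is unlikely too, since the median without it was 0.654, though called members then numbered 3 of 52. A response to nitrate remains a hypothesis, found and tested on the same data.

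Amino acid and peptide transporters had medians of −0.33 and −0.21 with NH4Cl against water and NaNO3. The libraries that stand apart do not carry this, since without both the medians were −0.363 against water and −0.292 against NaNO3. Ammonium lowering genes for other nitrogen sources may be the reason, and the lists of nitrate assimilation, other nitrogen source use and secreted peptidases had 5 of 6 medians below 0, secreted peptidases standing at 0.08 against NaNO3. Against water, 0 of 70 genes of other nitrogen source use were called (camera adjusted p = 0.259). The 6 medians were required to be below 0, so this was left undecided, and a difference of ammonium from other causes tied to NH4Cl, such as pH, cannot be told apart from it in this design.

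Whether other groupings of the libraries give as many calls was counted over the 10 splits of each 6 libraries into 3 and 3. In each comparison 1 split, the real one, gave as many: 100 calls with NH4Cl against water (highest other 3), 749 with NaNO3 against water (highest other 1) and 162 with NH4Cl against NaNO3 (highest other 1). With 10 splits a share under 0.05 cannot be reached.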
